A study of Danio rerio with 9 samples.

How the data were processed

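Gene expression was measured on 9 Affymetrix 3' IVT zebrafish arrays, 1 per sample, in neurons sorted by fluorescence from dissociated adult zebrafish brain. Per the labels' protocols, total RNA was isolated with a miRNeasy Micro kit, amplified with the Ovation Pico WTA system and labelled with biotin. The 3 groups of 3 arrays are unlesioned, nonregenerated and regenerated, taken from the labels, which call the samples of a group biological replicates.

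The deposited values are on a log2 scale. The authors computed them with RMA, per the submitters' processing notes, and its version is not given in the sources used here. The median of each of the 15617 probe sets over the 9 arrays was 0 (tolerance 1e-04), so each deposited log2 value is a difference from that probe set's own median. The step that centred the probe sets is not given in the sources used here. Differences between groups are unaffected by this centring, but no absolute level or signal over background is known, and a fold change is on the RMA log2 scale. Values ran from -5.52 to 5.93.

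The 115 control probe sets were left out, and 15502 probe sets were tested. A table of platform annotation named 1 gene symbol for 10795 of them, several for 135 and none for 4572. Symbols were updated through gene identifiers found in the RefSeq table (assembly GRCz12tu, used for names only) for 10711 probe sets, which replaced 1 symbol. The named probe sets stand for 8793 genes. Among the tested probe sets, 471 carry a suffix that marks possible cross-hybridization between related transcripts. No coordinates are given, since no genome was used here.

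Group means were fitted to all 9 arrays in a single limma model (limma 3.58.1, R 4.3.3) with moderated variances (6 residual and 3.16 prior degrees of freedom). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Errors beside log2 changes are standard errors from this model, and all p-values are two-sided. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 32 lists. Camera with an estimated correlation and limma's fry were run beside it. Of 33 lists drawn up for pathways of injury and axon growth and for cell types that a sort of brain cells could hold, 1 had fewer than 5 measured genes. Genes of a list and the fixed genes were given the mean of their probe sets, adjusted over the 8793 genes. The plan had named the probe set of highest mean for this, which centred values do not allow, so the mean of the probe sets was used.

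The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls among called probe sets with 1 informative symbol and no overlap between the groups' arrays. Where fewer than 4 qualified in a direction it was filled to 4 by the smallest p. It also took up to 4 members with the smallest p from each list described, and 21 fixed genes, of which 17 were measured.

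The model was tested on simulated arrays with the measured spread of the 15502 probe sets, with 200 of them changed in the regenerated against the nonregenerated arrays. It recovered 27.4% of changes of 1 on the log2 scale, 89.0% of changes of 2, 99.6% of changes of 3 and 100% of changes of 4 over 10 runs, and 4.13% of its calls were false. Camera called a list shifted by -1 in 10 of 10 simulated runs on 8793 genes and none of the 300 unshifted lists tested. These runs were built from measured spreads and do not show how the preset holds where genes move together. In the measured arrays no list was called in any comparison with an estimated correlation.

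Alternatives covered array scaling, array weights, the arrays entering the fit, each array left out in turn, thresholds, 1 value per gene, and the replicate number as a block. Alternatives added after seeing the data were robust moderation, centring each array on its median, the negative control reading as a covariate, leaving out regenerated arrays 1 and 3, the probe set with the largest SD for each gene, and any rescaling of the arrays before the tests of gene lists. Negative controls are 22 control probe sets for sequences outside the zebrafish genome. Marker lists for Purkinje and cerebellar granule cells were also written after the data were seen. The number of arrays limits the precision given here. Figures were drawn with matplotlib 3.10.9.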

Results

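Adult zebrafish regrow some, but not all, of the axons that descend from the brain after the spinal cord is severed. The study asked which genes distinguish brain neurons that regrew an axon. Fish received a complete cord transection at vertebra 8 together with Fluororuby, a red dextran that is carried back along axons to the cell body. A green tracer, Fluoroemerald, was placed 4 mm beyond the lesion 3 weeks later to mark neurons with a regrown axon, and cells were sorted after 1 more week. Lesioned fish gave the regenerated and the nonregenerated neurons, and whether samples of these 2 groups came from the same fish is not given in the sources used here. Neurons of unlesioned fish, marked by Fluororuby placed at that vertebra, were collected after 1 week. Time since the first tracer thus differs between the lesioned and the unlesioned groups. Each group has 3 arrays, and this number limits the precision of every value.

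The regenerated arrays stood apart from the other 6. The first principal component held 33.4% of the variance. The regenerated arrays scored 35.3, 55.4 and 49.3 on it, and the others lay between -31.2 and -12.8. The second component held 15.9% and did not order the groups. The SD over probe sets was 0.626 ± 0.0285 in the regenerated arrays, 0.383 ± 0.0420 in the unlesioned and 0.410 ± 0.0169 in the nonregenerated arrays (mean ± SD, n = 3 each). The median reading of the 22 negative control probe sets was 0.27 ± 0.22 in the regenerated arrays, -0.04 ± 0.11 in the unlesioned and -0.06 ± 0.09 in the nonregenerated arrays. It reached 0.48 in regenerated array 1, 0.04 in array 2 and 0.28 in array 3. The log2 difference between the 3' and 5' probe sets of a control transcript is a measure of RNA quality. It was taken here from centred values, so it compares arrays and gives no absolute ratio of 3' to 5' signal. For the actin control it was -0.77, -0.08 and 0.57 in regenerated arrays 1, 2 and 3 (SD 0.67), with 0.04 ± 0.06 in the unlesioned and 0.09 ± 0.14 in the nonregenerated arrays. For the GAPDH control it was -0.03 ± 0.29, 0.20 ± 0.35 and -0.03 ± 0.27 in the same order of groups.

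**Figure D1:**
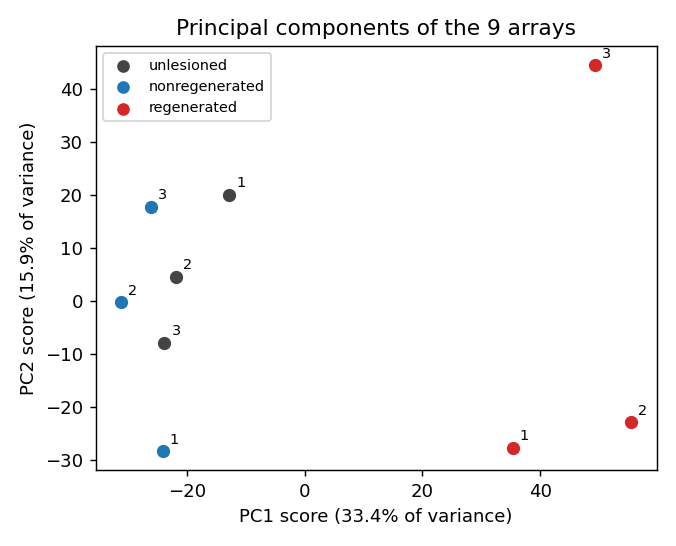
Scores of the 9 arrays on the first 2 principal components of the 15502 probe sets, with 33.4% and 15.9% of the variance on the axes. Each point is an array, coloured by group and marked with its replicate number, and the 3 regenerated arrays lie at scores of 35.3 to 55.4 on the first component.

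Regenerated neurons were compared with nonregenerated neurons, both from lesioned fish, for genes that go with regrowth. Among called probe sets with a gene symbol, the 8 largest rises included genes known from cerebellar Purkinje neurons, and the 8 largest falls included sox9b, sox2, olig2 and gpm6bb beside aplnra, foxb1a, musk and sema5a. The metabolic enzyme aldolase C (aldoca), the zebrin II antigen of Purkinje cells, rose by 6.33 ± 0.87 on the log2 scale, or 80.5-fold. The calcium-binding parvalbumin pvalb7 rose by 5.96 ± 0.54 and pcp4l1, a relative of Purkinje cell protein 4, by 5.21 ± 0.53. The carbonic anhydrase relative ca8 rose by 3.91 ± 0.43. Both measured probe sets of ca8 showed this, the other at 3.90. The diacylglycerol kinase gene dgkzb rose by 4.52 ± 0.34, the kinase gene camk2d1 by 4.03 ± 0.35 and the calcium store gene casq2 by 3.94 ± 0.34. The transcriptional cofactor gene pbxip1b rose by 3.71 ± 0.33. Adjusted p-values of these 8 genes ran from 0.000517 for dgkzb to 0.00716 for aldoca.

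Among the falls, the apelin receptor gene aplnra changed by -3.95 ± 0.28 and the glial transcription factor gene sox9b by -3.93 ± 0.36. The forkhead gene foxb1a changed by -3.90 ± 0.37, the receptor kinase gene musk by -3.72 ± 0.59 and the progenitor gene sox2 by -3.57 ± 0.57. The oligodendrocyte lineage gene olig2 changed by -3.35 ± 0.46, the guidance gene sema5a by -3.24 ± 0.61 and gpm6bb, a gene of the proteolipid family, by -3.17 ± 0.43. Their adjusted p-values ran from 0.000517 for aplnra to 0.0289 for sema5a. Other probe sets of sox9b and sox2 fell less, by 1.82 for sox9b and by 1.27 to 1.75 for sox2. In all, 380 of 15502 probe sets were called, 162 higher and 218 lower, and in each of the 380 every regenerated array lay on the same side of every nonregenerated array. Groups failed to overlap in 21.8% of all probe sets, where chance gives 10%. An unadjusted p under 0.05 was reached by 2515 probe sets, where 775 are expected by chance.

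**Figure D2:**
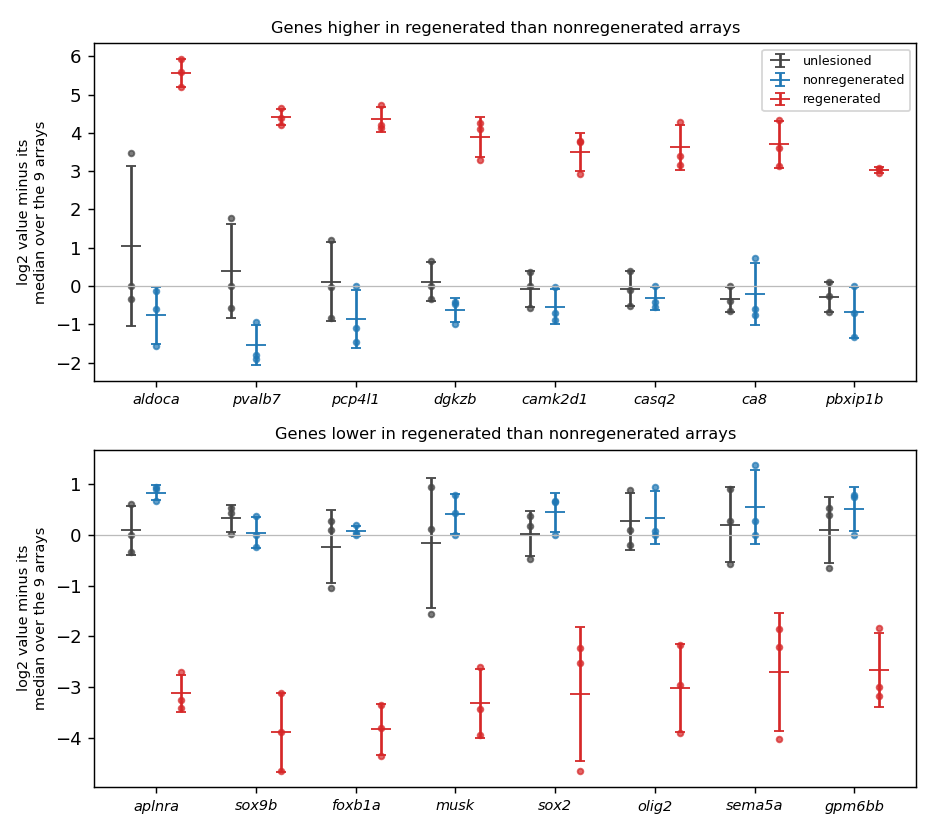
Log2 values, as differences from each probe set's median over the 9 arrays, of the 8 largest rises (top) and 8 largest falls (bottom) of regenerated against nonregenerated arrays among called probe sets with 1 informative symbol and no overlap between the groups. Points are arrays and bars are the mean and SD of 3 arrays per group, and for aldoca the regenerated mean is 5.57 ± 0.37 against -0.77 ± 0.74 in nonregenerated arrays.

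Markers of radial glia and astroglia fell as a list. The median change of its 28 measured genes was -1.23, and 10 fell and none rose over all genes, with 17 lower and none higher adjusted over the list alone. Camera gave an adjusted p of 1.74e-14, and adjusted p = 0.144 with an estimated correlation. Examples are sox9a at -2.44 ± 0.24, the hairy-related gene her6 at -1.92 ± 0.27 and the sodium pump gene atp1a1b at -2.43 ± 0.35. Oligodendrocyte and myelin genes had a median of -1.18 over 12 genes, with 4 lower (7 adjusted over the list alone), at an adjusted p of 9.37e-07, and adjusted p = 0.0716 with an estimated correlation. The lineage genes sox10 and nkx2.2a changed by -3.15 ± 0.39 and -1.85 ± 0.29. Of the 12 genes 2 had point estimates above 0, and the fixed myelin gene mbpa had 0.28 ± 0.48, not called. Leukocyte markers did not pass, with a median of -0.08 over 29 genes (adjusted p = 0.758).

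Pan-neuronal markers were higher in the regenerated neurons, with a median of 0.51 over 27 genes, at an adjusted p of 1.27e-05, and adjusted p = 0.310 with an estimated correlation. Among them 8 rose and none fell (10 and none adjusted over the list alone), including the sodium pump gene atp1a3b at 3.48 ± 0.44, the calcium pump gene atp2b1a at 2.72 ± 0.24, the G protein gene gng3 at 1.36 ± 0.16 and atp1b2a at 1.22 ± 0.21. Genes of synaptic vesicles and release had a median of 0.50 over 24 genes, with 3 higher (9 higher and 2 lower adjusted over the list alone), at an adjusted p of 0.000918, and adjusted p = 0.328 with an estimated correlation. The release gene snap25b rose by 2.06 ± 0.41 and the vesicle GTPase gene rab3c by 2.21 ± 0.35. Markers of GABAergic and glycinergic neurons had a median of 0.71 over 14 genes (adjusted p = 0.00301, and adjusted p = 0.309 with an estimated correlation), of which pvalb7, pvalb6 and gad1b rose. On the list alone 5 were higher and 1 lower. pvalb6 rose by 3.13 ± 0.48, and gad1b, the enzyme that makes GABA, by 1.61 ± 0.35. Voltage-gated ion channels had a median of 0.54 over 10 genes (adjusted p = 0.00945, and adjusted p = 0.205 with an estimated correlation), a call lost at 0.63 without nonregenerated array 3. None of the 10 passed over all genes and 5 were higher adjusted over the list alone, scn3b at 1.09 ± 0.25 among them.

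Genes of oxidative phosphorylation had a median of 0.57 over 72 genes at an adjusted p of 3.01e-13, and adjusted p = 0.310 with an estimated correlation. Over all genes 3 rose and 1 fell, and 22 were higher and 1 lower adjusted over the list alone. The respiratory chain genes cox4i1l and cox6b1 rose by 2.60 ± 0.20 and 2.37 ± 0.26, and cox4i2 changed by -1.79 ± 0.40. Glycolysis genes had a median of 0.25 over 28 genes (adjusted p = 0.0496, and adjusted p = 0.463 with an estimated correlation). Its 4 called genes went both ways, with aldoca and the lactate dehydrogenase gene ldhbb (2.74 ± 0.34) higher and eno1b (-2.51 ± 0.32) and pfklb (-1.79 ± 0.25) lower, and the same counts were found adjusted over the list alone. Its call was lost at a median of 0.25 without unlesioned array 1, 0.22 without nonregenerated array 1, 0.34 without nonregenerated array 3, 0.29 without regenerated array 2 and 0.19 without regenerated array 3. It was also lost at 0.19 after a further quantile normalization, 0.30 with the probe set of largest SD for each gene, 0.21 without regenerated arrays 1 and 3 together, and with fry. Skeletal muscle genes had a median of 0.27 with none of 28 called on either adjustment (adjusted p = 0.0188, and adjusted p = 0.580 with an estimated correlation). With the negative control reading as a covariate their median was 0.02 and the call was lost, as it was at 0.23 without nonregenerated array 1, 0.19 without regenerated array 1, 0.23 without regenerated array 3, 0.08 without both of these, and with fry.

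Axon guidance and adhesion genes were lower in the regenerated neurons, with a median of -0.28 over 46 genes at an adjusted p of 6.67e-05, and adjusted p = 0.0716 with an estimated correlation. Of these 5 fell and none rose (8 and none adjusted over the list alone). The repulsive guidance gene rgmd changed by -2.27 ± 0.25, the matrix gene tnr (tenascin-R) by -2.28 ± 0.27 and the receptor phosphatase gene ptprsa by -1.63 ± 0.29. The list of genes known from axon regeneration in other systems had a median of -0.27 over 57 genes (adjusted p = 0.00455, and adjusted p = 0.0716 with an estimated correlation). Over all genes 2 rose and 5 fell, with 4 higher and 7 lower adjusted over the list alone. The urokinase gene plaua rose by 3.31 ± 0.45, and mycb, marcksb and tuba1b changed by -1.24 ± 0.22, -1.43 ± 0.28 and -2.09 ± 0.44. Sterol synthesis genes had a median of -0.53 over 12 genes (adjusted p = 0.00598, and adjusted p = 0.328 with an estimated correlation), with 1 lower over all genes, insig1 at -1.71 ± 0.25, and 3 lower adjusted over the list alone. The calls of the last 2 lists were lost with the negative control covariate, and that of sterol synthesis also without regenerated arrays 1 and 3 and with fry. The other 20 lists were not called (smallest adjusted p = 0.0629).

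**Figure D3:**
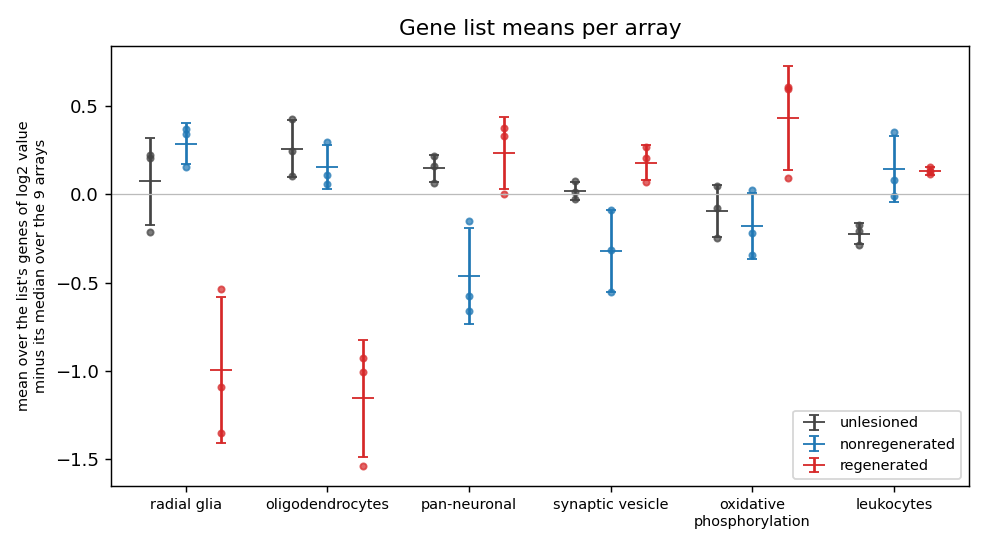
Mean over a list's genes of the log2 values, as differences from each probe set's median over the 9 arrays, for 6 gene lists. Points are arrays and bars are the mean and SD of 3 arrays per group, and the radial glia mean is -0.99 ± 0.41 in the regenerated arrays against 0.18 ± 0.21 over the other 6.

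The count of 380 fell to 181 without nonregenerated array 2 and to 197 without nonregenerated array 3, rose to 572 without regenerated array 1, and was 183 with the negative control reading as a covariate and 176 after a further quantile normalization. Quantile normalization narrows the wider regenerated arrays, so a lower count can follow from that step itself. Of the called probe sets 42.6% were higher, against 128 higher and 342 lower when each array was centred on its 75th percentile, which shifted the median of all probe sets by -0.12, and 60.1% with the covariate. Leaving out 1 array at a time ended the calls of stmn2a and cox4i2 in 8 of 9 runs, of gad1b, marcksb and tuba1b in 6, of snap25b in 5, of sema5a and ptprsa in 4, of mycb in 3 and of atp1b2a in 2. Those of sox2 and rab3c were lost without nonregenerated array 3 (sox2 at -3.46) and that of musk without nonregenerated array 2 (-3.71). The call of aldoca held in each of the 9 runs but was lost in 3 of all 20 alternatives (highest limma adjusted p = 0.0684).

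Regenerated neurons were next compared with neurons of unlesioned fish. Among called probe sets with a symbol, the 8 largest rises were of the same 8 genes, with aldoca at 4.52 ± 0.87, ca8 at 4.27 ± 0.49, pcp4l1 at 4.24 ± 0.53, pvalb7 at 4.01 ± 0.54, dgkzb at 3.78 ± 0.34, casq2 at 3.69 ± 0.34, camk2d1 at 3.56 ± 0.35 and pbxip1b at 3.31 ± 0.33. Their adjusted p-values ran from 0.00278 for dgkzb and casq2 to 0.0358 for aldoca. Values of aldoca in unlesioned arrays ran from -0.33 to 3.46, and its call was lost in 8 of 9 runs that each left out an array. The 8 largest falls were of sox9b at -4.21 ± 0.36, the tubulin gene tuba8l3 at -3.73 ± 0.55, foxb1a at -3.60 ± 0.37 and the brain aromatase gene cyp19a1b at -3.43 ± 0.54. They were followed by olig2 at -3.27 ± 0.46, aplnra at -3.21 ± 0.28, musk at -3.15 ± 0.59 and sox2 at -3.15 ± 0.57. Other probe sets fell less, with -2.20 for sox9b, -1.68 and -1.30 for cyp19a1b and -1.83 and -1.45 for sox2, and the other of ca8 rose by 4.04. The call of musk was lost in 6 of the 9 runs that each left out an array, and that of cyp19a1b in 4. In all 344 probe sets were called, 135 higher and 209 lower, each with no overlap between the groups' arrays, and 2310 reached an unadjusted p under 0.05. Groups failed to overlap in 19.6% of all probe sets, against 10% by chance.

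The marker lists moved much as in the first comparison for glia. Radial glia and astroglia had a median of -1.04 with 7 of 28 lower (17 adjusted over the list alone), at an adjusted p of 2.18e-11, and adjusted p = 0.231 with an estimated correlation. The glial genes sox9a and sox19a changed by -2.40 ± 0.24 and -2.19 ± 0.39. Oligodendrocyte genes had a median of -1.43 with 5 of 12 lower (7 adjusted over the list alone), at an adjusted p of 3.36e-08, and adjusted p = 0.0600 with an estimated correlation. Here sox10 changed by -2.97 ± 0.39, gpm6bb by -2.75 ± 0.43 and nkx2.2a by -1.61 ± 0.29. Leukocyte markers were higher as a list, with a median of 0.30 over 29 genes (adjusted p = 0.00266, and adjusted p = 0.289 with an estimated correlation). Of these apoeb rose (0.95 ± 0.20, adjusted p = 0.0405), with 2 higher adjusted over the list alone, and the lysozyme gene lyz did not pass at -2.81 ± 0.90. Pan-neuronal markers were not called (median 0.02, adjusted p = 0.716).

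Axon guidance and adhesion genes had a median of -0.35 with 4 of 46 lower (9 adjusted over the list alone), at an adjusted p of 2.62e-06, and adjusted p = 0.0600 with an estimated correlation. These were tnr at -2.56 ± 0.27, rgmd at -1.73 ± 0.25, ptprsa at -1.44 ± 0.29 and sema5a at -2.89 ± 0.60. Oxidative phosphorylation had a median of 0.47 with 2 of 72 higher (12 higher and 1 lower adjusted over the list alone), at an adjusted p of 1.06e-10, and adjusted p = 0.372 with an estimated correlation, and cox4i1l rose by 2.09 ± 0.20 and cox6b1 by 1.77 ± 0.26. It did not pass fry (adjusted p = 0.0614). Regeneration-associated genes had a median of -0.09 with 1 of 57 higher and 4 lower (2 and 10 adjusted over the list alone), at an adjusted p of 0.0272, and adjusted p = 0.188 with an estimated correlation. In it plaua rose by 3.10 ± 0.45, and marcksb, tuba1b and gadd45aa changed by -1.95 ± 0.28, -2.44 ± 0.44 and -1.63 ± 0.31. This call was lost with each array centred on its 75th percentile, after quantile normalization, with the covariate, and at a median of -0.18 without unlesioned array 2, -0.19 without unlesioned array 3, -0.09 without regenerated array 2, -0.12 without regenerated array 3 and -0.14 without regenerated arrays 1 and 3, with adjusted p-values from 0.0115 to 0.188 over all alternatives. Sterol synthesis genes had a median of -0.61 with 1 of 12 lower on either adjustment, insig1 at -1.68 ± 0.25 (adjusted p = 0.00161, and adjusted p = 0.289 with an estimated correlation). It was lost with the covariate, without regenerated arrays 1 and 3, and with fry.

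Cytosolic ribosomal protein genes had a median of 0.24 over 70 genes with none called on either adjustment (adjusted p = 0.000898, and adjusted p = 0.608 with an estimated correlation), rps29 at 0.95 ± 0.36 among them. The call was lost with the covariate and at 0.13 without unlesioned array 2. Glycolysis genes had a median of 0.29 with 2 of 28 higher and 2 lower on both adjustments (adjusted p = 0.0260, and adjusted p = 0.392 with an estimated correlation), where ldhbb rose by 2.32 ± 0.34 and eno1b and pfklb changed by -1.72 ± 0.32 and -1.37 ± 0.25. That call was lost at 0.23 without unlesioned array 1 and 0.23 without regenerated array 3. Proteasome and skeletal muscle genes had medians of -0.22 over 32 genes and 0.22 over 28 genes with none called on either adjustment, each at an adjusted p of 0.0260, and at adjusted p = 0.566 with an estimated correlation. The proteasome call was lost with the covariate and at -0.25 without unlesioned array 3 and -0.06 without regenerated array 1. The muscle call was lost with the covariate, where the median was -0.01, and at 0.18 without unlesioned array 3, 0.15 without regenerated array 1 and 0.21 without regenerated array 3. The calls of these 4 lists were also lost without regenerated arrays 1 and 3 together, and with fry. The other 21 lists were not called by camera (smallest adjusted p = 0.0595). Among them, immediate-early and heat-shock genes (median 0.23, adjusted p = 0.0277) and monoaminergic and cholinergic markers (-0.22, adjusted p = 0.0399) passed fry.

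Without unlesioned arrays 1, 2 or 3 the count of 344 became 173, 107 or 58. It was 220 and 228 without nonregenerated arrays 2 and 3, 137 and 218 without regenerated arrays 2 and 3, 130 with the negative control covariate and 96 after a further quantile normalization. The count after quantile normalization has the same limit as in the first comparison. Of the called probe sets 39.2% were higher, against 26.0% with each array centred on its 75th percentile, which shifted the median of all probe sets by -0.11, and 54.6% with the covariate. Leaving out 1 array at a time ended the call of apoeb in 9 of 9 runs, of sema5a in 8, of gadd45aa and ptprsa in 6, of tuba1b and eno1b in 4, and of sox2, sox19a, nkx2.2a, gpm6bb and pfklb in 3. Calls of pvalb7, olig2, tuba8l3, plaua, ldhbb and insig1 were lost without unlesioned array 3, where pvalb7 had 3.81 and olig2 -2.96, and that of tuba8l3 also without unlesioned array 2 (-3.62).

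Nonregenerated neurons were compared with those of unlesioned fish for changes after injury. Their name rests on the tracer placed 4 mm beyond the lesion, so shorter regrowth is not excluded. No probe set passed in limma's test (smallest adjusted p = 0.369). An unadjusted p under 0.05 was reached by 790 probe sets, 376 higher and 414 lower, where 775 are expected by chance, and groups failed to overlap in 11.1%, against 10% by chance. The 4 probe sets of smallest p in each direction are given as values. The neuronal transcription factor gene tbr1b had a change of -1.46 ± 0.19, the haemoglobin genes hbba2 and hbaa1 of -3.72 ± 0.61 and -3.29 ± 0.56, and cyp19a1b of -1.82 ± 0.32. The injury-responsive factor gene cebpd had 1.70 ± 0.24, sec14l1 1.30 ± 0.26, the inflammasome adaptor gene pycard 1.39 ± 0.29 and the protease gene napsa 1.00 ± 0.20. The other probe set of cebpd had 0.47, and the other 2 of cyp19a1b had -2.31 and -1.48.

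Camera called 13 lists at the preset correlation, with no member gene called over all genes in any of them and none of the 13 called with an estimated correlation (smallest adjusted p = 0.128). Pan-neuronal markers had a median of -0.60 over 27 genes, all 27 with point estimates below 0 and 10 lower adjusted over the list alone, at an adjusted p of 3.80e-14, and adjusted p = 0.128 with an estimated correlation. Values of stmn2a, gng3 and snap25b were -0.94 ± 0.21, -0.60 ± 0.16 and -1.46 ± 0.41. Synaptic vesicle genes had a median of -0.40 over 24 genes (adjusted p = 1.80e-05, and adjusted p = 0.247 with an estimated correlation), GABAergic and glycinergic markers of -0.47 over 14 (0.00269, and adjusted p = 0.247 with an estimated correlation) and voltage-gated ion channels of -0.26 over 10 (0.00712, and adjusted p = 0.231 with an estimated correlation), with 1 synaptic gene lower adjusted over the list alone. Axonal cytoskeleton genes had a median of -0.22 over 35 (0.00712, and adjusted p = 0.294 with an estimated correlation) and regional transcription factors of hindbrain and midbrain of -0.10 over 75 (0.0251, and adjusted p = 0.588 with an estimated correlation), with none called adjusted over the list alone. Erythrocyte genes had a median of -0.41 over 19, with 3 lower adjusted over the list alone (1.45e-05, and adjusted p = 0.247 with an estimated correlation), where slc4a1a had -2.07 ± 0.39. Calls ended for ion channels at -0.18 without nonregenerated array 3, for GABAergic and glycinergic markers at -0.38 without unlesioned array 3 and -0.28 without nonregenerated array 3, for the cytoskeleton at -0.20 without unlesioned array 3 and -0.11 without nonregenerated array 2, and for regional factors at -0.02 without unlesioned array 1, -0.06 without nonregenerated array 1, -0.08 after a further quantile normalization and -0.09 with the covariate.

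Lists with higher medians included leukocyte markers at 0.50 over 29 genes (adjusted p = 3.44e-07, and adjusted p = 0.128 with an estimated correlation), with cxcr4b at 0.92 ± 0.29 and lyz at -2.73 ± 0.90. Immediate-early and heat-shock genes had a median of 0.27 over 35 genes (0.000863, and adjusted p = 0.128 with an estimated correlation). It alone of the 13 also passed fry (adjusted p = 0.0144), with dusp2 at 0.71 ± 0.23 and ier5 at 0.62 ± 0.23. The list is not particular to nonregenerated neurons. In regenerated against unlesioned neurons its median was 0.23, and it passed fry (adjusted p = 0.0277) but not camera (adjusted p = 0.156). Between the lesioned groups its median was -0.05 (camera adjusted p = 0.466). Genes of endoplasmic reticulum stress had a median of 0.23 over 24 (0.000668, and adjusted p = 0.247 with an estimated correlation), xbp1 at 0.64 ± 0.24 among them. Ribosomal protein genes had 0.26 over 70 (1.06e-08, and adjusted p = 0.465 with an estimated correlation) and translation and mTOR genes 0.16 over 53 (0.0201, and adjusted p = 0.388 with an estimated correlation). Radial glia had 0.22 over 28 (0.0197, and adjusted p = 0.588 with an estimated correlation), although its genes of smallest p went both ways, with slc1a3a at 1.21 ± 0.32 and her6 at 0.86 ± 0.27 against cyp19a1b at -1.87 ± 0.34 and vim at -1.19 ± 0.41. Adjusted over the list alone, 1 radial glia gene was lower and no gene of the other 5 lists passed. Calls ended for radial glia at 0.05 without unlesioned array 1 and 0.23 without nonregenerated array 2 and for translation at 0.12 without unlesioned array 1, 0.11 without unlesioned array 2 and 0.21 without nonregenerated array 1. The other 19 lists were not called (smallest adjusted p = 0.0629).

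Genes known from axon regeneration and from glia were fixed for every comparison, and 17 were measured. Against unlesioned neurons apoeb was the only call in the regenerated neurons, and it was lost in each of 9 runs that left out an array. None was called in the nonregenerated neurons. The axonal growth gene gap43 had changes of -0.99 ± 0.29 in regenerated and -0.43 ± 0.29 in nonregenerated neurons. The stress factor gene atf3 had 0.88 ± 0.31 and 0.71 ± 0.31, jun 0.10 ± 0.18 and 0.49 ± 0.18, socs3a 0.84 ± 0.31 and 0.86 ± 0.31, and stat3 0.65 ± 0.27 and 0.86 ± 0.27. The paralogue socs3b had -0.02 ± 0.40 and 0.31 ± 0.40. The growth-related factor genes sox11a and sox11b had -0.61 ± 0.23 and -0.19 ± 0.26 in regenerated and -0.35 ± 0.23 and -0.37 ± 0.26 in nonregenerated neurons, and klf6a and klf7b had -0.29 ± 0.30 and -0.77 ± 0.38, against 0.33 ± 0.30 and 0.15 ± 0.38. The adhesion genes l1camb and cntn2 had 0.06 ± 0.46 and 0.41 ± 0.46 in regenerated and -0.37 ± 0.46 and -1.12 ± 0.46 in nonregenerated neurons. The glial genes gfap and mbpa had -0.36 ± 0.28 and -0.51 ± 0.48, against 0.80 ± 0.28 and -0.79 ± 0.48. The neuronal RNA-binding gene elavl3 had -0.81 ± 0.23 and -0.78 ± 0.23. Between the lesioned groups only the neuronal tubulin regulator gene stmn2a was called, higher in regenerated neurons by 0.95 ± 0.21 (adjusted p = 0.0462, lost in 8 of 9 such runs), with 0.01 ± 0.21 and -0.94 ± 0.21 against unlesioned neurons. gfap had -1.16 ± 0.28 in that comparison (adjusted p = 0.0604).

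Both comparisons with unlesioned neurons share 3 control arrays. No probe set was called in both, since the nonregenerated comparison had no calls. At an unadjusted p under 0.01 and at least 2-fold, 708 and 101 probe sets passed and 25 passed in both in the same direction. Unchanged groups simulated against the same controls shared 9.52 on average and at most 19 in 50 runs, and independent lists of these sizes share 2.47. The covariance of the log2 changes was 0.0429, no higher than the 0.0515 that shared controls gave in the simulation. By that measure no shared change beyond the controls was seen. Both simulated groups were unchanged, while the regenerated comparison had many changes, so 25 and 9.52 are not like for like. The 3 controls are too few to be split into separate sets of at least 2, so how much of the 25 comes from them is not known. The 2 comparisons with regenerated neurons share the 3 regenerated arrays, and 230 of their calls were shared in the same direction. At an unadjusted p under 0.01 and at least 2-fold, 491 were shared, where independent lists share 20.7 and simulated unchanged groups 9.70 on average and at most 21. Their covariance was 0.288 against 0.0516 in the simulation.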

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

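The test of glial against leukocyte genes was chosen only after the result was seen, and its condition on varying leukocyte genes was added after the test had first been run. The rule that picked lists differing between the lesioned groups first asked for camera alone, and fry was added to it later. The negative control covariate was chosen after the data were seen, though before its value for the glial genes was. The splits of the arrays were chosen before their results.

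The negative control probe sets, which the comparisons do not use, read above the highest unlesioned array in regenerated array 1 (0.48) and regenerated array 3 (0.28).

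For 7 lists the median change against unlesioned neurons had opposite signs in the lesioned groups, and the difference between those groups passed camera at the preset correlation and fry. None of the 7 passed camera with an estimated correlation. The median over a list's genes of the change between the lesioned groups need not equal the difference of the medians against unlesioned neurons. This median, regenerated minus nonregenerated, was 0.51 for pan-neuronal markers, 0.71 for GABAergic and glycinergic markers, 0.54 for voltage-gated ion channels and 0.50 for synaptic vesicle genes. It was 0.57 for oxidative phosphorylation, -0.27 for regeneration-associated genes and -1.23 for radial glia and astroglia. Some of the signs rest on medians near 0. Against unlesioned neurons pan-neuronal markers had 0.02 in regenerated and -0.60 in nonregenerated neurons, and regeneration-associated genes -0.09 and 0.04. Pan-neuronal, synaptic vesicle (0.14), ion channel (0.16) and GABAergic and glycinergic (0.25) lists were not called in regenerated against unlesioned neurons. In nonregenerated neurons these lists were called lower.

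Glial and oligodendrocyte genes were lower in the regenerated arrays, and the mean of the 40 genes of both lists differed from the other 6 arrays by -1.23 (exact permutation p = 0.0119, two-sided, the smallest that 84 ways to take 3 of 9 arrays give). A purer sort of neurons would lower markers of other cell types alike, but leukocyte genes differed by 0.18 (exact permutation p = 0.274). The 23 of them that varied at least as much as the median gene differed by 0.19. Means of endothelium and pericyte (0.31), meninges and fibroblast (-0.05), erythrocyte (-0.02) and skeletal muscle genes (0.22) did not fall as the glial genes did. Glial minus leukocyte genes differed by -1.41 (exact permutation p = 0.0119), which largely repeats the glial difference. These values cannot exclude a purer sort, since centred values do not tell whether leukocyte genes or those of the other cell types were measured above background. Pan-neuronal markers had a median of 0.51 against nonregenerated but 0.02 against unlesioned neurons. Background hybridization as the whole source of the lower glial genes is argued against by the negative control covariate. With it the median of the 40 genes against nonregenerated arrays went from -1.23 to -1.51. That covariate has a correlation of 0.769 with being a regenerated array, which limits how well the model parts them. A lower share of glia alone may account for the pattern, as may a difference between the sorted neurons, and neither was tested.

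Among the 84 ways to take 3 of the 9 arrays, only 1, the regenerated arrays, called as many as 681 probe sets against the other 6. The highest other count was 3. Chance in the grouping is thus unlikely for the regenerated arrays against the rest, though 1 in 84 is the smallest share possible. The splits do not tell regrowth from anything else those 3 arrays share, such as a hybridization batch, which is not given in the sources used here. For single comparisons 10 splits of 6 arrays are too few for a share under 0.05. Regenerated against unlesioned gave 344 with 1 as the highest other count, regenerated against nonregenerated gave 380 with 0, and nonregenerated against unlesioned gave 0 in all 10 splits.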

How the results depend on the processing

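Robust moderation, array median centring, the negative control covariate, leaving out regenerated arrays 1 and 3, the probe set of largest SD, and rescaling before the list tests were chosen after seeing the data. Not run, since centred values hold no absolute level, were the trend in the moderation, filters on dim probe sets, cyclic loess and the choice of probe set by highest mean. Centring on the 75th percentile and quantile normalization acted on centred values, which spread more widely in the regenerated arrays (SD 0.626 against 0.383 in unlesioned and 0.410 in nonregenerated arrays). Quantile normalization narrows that spread, so fewer calls after it can follow from the step itself. The 75th percentiles of regenerated arrays ran from 0.23 to 0.31, against 0.13 to 0.21 in the others, so centring on them shifts the regenerated arrays down. Signal over background is unknown for the same reason. Of named genes and lists with a call on either side, 1 list changed the sign of its median under an alternative run: skeletal muscle, regenerated against unlesioned, went from 0.22 to -0.01 with the covariate, without a call there. The cause of the changes below was not tested except where fewer arrays or another threshold make it.

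Calls of regenerated against unlesioned numbered 344. They were 96 after quantile normalization (94 shared with the 344), 130 with the negative control covariate (90 shared), 158 with only the 6 arrays compared, 199 with 1 value per gene, 567 at an adjusted p under 0.10 and 708 at an unadjusted p under 0.01 and 2-fold. Leaving out each array gave 58 to 418. Calls of regenerated against nonregenerated numbered 380. They were 176 after quantile normalization (all 176 shared), 183 with the covariate (119 shared), 224 with only the 6 arrays compared, 789 at an adjusted p under 0.10 and 855 at an unadjusted p under 0.01 and 2-fold. Leaving out each array gave 181 to 572. Without regenerated arrays 1 and 3 the counts were 411 and 481, of which 161 and 201 were shared, and the lone regenerated array is then assumed to vary like the other groups. Nonregenerated against unlesioned had 0 calls, 101 at an unadjusted p under 0.01 and 2-fold, and 0 to 1 when each array was left out, the 1 being lyz without unlesioned array 2, named after its value was seen (-4.07 ± 0.27). Overlap of the comparisons with unlesioned went from 0 to 25 at the unadjusted threshold.

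Lists called numbered 11, 13 and 12 for regenerated against unlesioned, nonregenerated against unlesioned and regenerated against nonregenerated. With an estimated correlation they were 0, 0 and 0, and with fry 7, 1 and 9. Without regenerated arrays 1 and 3 the first was 5. Leaving out each array gave 8 to 12, 11 to 14 and 10 to 13.

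With the replicate number as a block (replicate block), calls were 193 for regenerated against unlesioned, 0 for nonregenerated against unlesioned and 280 for regenerated against nonregenerated, and lists called were 11, 14 and 12. As a random block calls were 294, 0 and 337, at a consensus correlation of -0.05. Same-numbered arrays of the lesioned groups had correlations of deviations from the group means of 0.12, -0.04 and 0.26, and not every array correlated best with its own number.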

Other observations

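All tests in this part were chosen only after the result was seen. For cells of Purkinje type, the first test took the regenerated against the other 6 arrays together and came out in favour. A condition on genes without a call then left it undecided, since those 15 genes differed by a median of 0.11, above 65.2% of random lists of such genes. That condition was dropped, since a call itself decides which genes it leaves, and the test was then split by comparison. For background hybridization, the covariate replaced a first test, the share of called rises above the negative controls, which calling itself had fixed.

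A list of 24 measured Purkinje cell genes had a median change of 1.18 in regenerated against nonregenerated neurons and 1.79 with the negative control covariate, so it did not shrink with the covariate. This cannot exclude background hybridization. The list was written after the data were seen and holds 5 genes named for their large rises, and the covariate correlates with being regenerated at 0.769. A hypothesis is that cells of Purkinje type were among the sorted regenerated cells, although a sort for a tracer placed in the spinal cord would leave out Purkinje cells, whose axons do not reach it. With the 5 genes named by size left out, the other 19 had a median change of 0.46 against nonregenerated neurons, above each of 10000 random lists of that size, but 0.0226 against unlesioned neurons, above 35.9% of them. Against unlesioned neurons 11 of the 19 had changes above 0. The mean of the 19 was nonetheless higher in each regenerated array (0.41, 0.41 and 0.36) than in the unlesioned arrays (-0.05, 0.15 and 0.03). The 22 cerebellar granule cell genes had medians of 0.15 against nonregenerated and -0.72 against unlesioned neurons. Against nonregenerated neurons rorab and foxp2 had -0.71 ± 0.19 and -0.98 ± 0.31, not called, while plcb4b and atp2b2 rose by 2.73 ± 0.43 and 2.73 ± 0.36. Against unlesioned neurons plcb4b and atp2b2 were also called, at 1.99 ± 0.43 and 1.98 ± 0.36, and rorab and foxp2 were not, at -0.82 ± 0.19 and -0.64 ± 0.31. Neuronal lists had medians as high against nonregenerated neurons, with 0.51 for pan-neuronal, 0.50 for synaptic vesicle and 0.71 for GABAergic and glycinergic markers. The 0.46, from a list written after the data were seen, is thus not particular to Purkinje genes. Cells of Purkinje type and a change within other neurons cannot be told apart here: 10 of the 24 genes also stand on another list, and centred values give no level for the most abundant genes.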
